A study of Xenopus tropicalis with 12 samples.

How the data were processed

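RNA-seq libraries were made from the intestine of Xenopus tropicalis tadpoles, a frog whose metamorphosis is driven by thyroid hormone. Wild-type tadpoles and tadpoles without thyroid hormone receptor alpha, TRα(-/-), came from the same parents. They were left untreated or exposed to 10 nM T3, the active form of thyroid hormone, for 18 h, at stages labelled 52 to 54. The 12 libraries form 4 groups of 3. Per the labels, the 3 libraries of a group are technical replicates of 1 RNA pool merged from several tadpoles. P-values therefore measure the spread between libraries of a pool and compare 4 pools. They carry no information on the spread between animals.

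The labels contradict one another for 6 of the 12 libraries. The column labels of the count table are contWT, contHomo, T3WT and T3Homo. By name these are wild type without T3, TRα(-/-) without T3, wild type with T3 and TRα(-/-) with T3. The sample titles and treatment labels describe the 3 contHomo libraries as wild type with T3 and the 3 T3WT libraries as TRα(-/-) without T3. Both sources give the same identity to the contWT and T3Homo libraries. The groups were named by the column labels before the data were examined, and each comparison is described under both readings. The interaction contrast, (T3Homo minus contHomo) minus (T3WT minus contWT), is the same number under either reading.

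The deposited values are whole-number counts of reads per gene, not normalized, for 19921 genes, per the file headers. Reads were aligned with STAR 2.5.3a and counted with featureCounts 1.4.6-p3, per the submitters' processing notes. The genome build, the annotation release, the strand setting and the handling of reads with several alignments are not given in the sources used here. Without a strand setting, reads of overlapping or antisense genes cannot be separated. Coordinates are those of the deposited table, on its own scaffolds. All 12 value columns of the table were used.

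The deposited table gives gene identifiers without names. The reference gene table, of assembly UCB_Xtro_10.0, paired 0 of the nuclear identifiers with a symbol. The label check on thra, thrb, klf9, thibz, dio3 and mmp11, and the 20 gene lists fixed before the data were examined, could therefore not be run. The gene lists covered T3 response, receptors and deiodinases, DNA replication, mitosis, stem cells, enterocytes, apoptosis, extracellular matrix, developmental signalling, stress, and markers of 10 other tissues or cell types. The 13 protein-coding genes of the mitochondrial genome were named because their start and end match those of the reference mitochondrial sequence. They were chosen after their values were seen. The rule for named genes took the 8 largest rises and 8 largest falls per contrast among called genes with a symbol, at a mean of at least 5 CPM (counts scaled by the effective library size) in the higher group and without overlap between the libraries of the groups. No nuclear gene met the symbol condition. The rule was applied without it, and the first 2 identifiers in each direction of T3WT vs contWT are given. Runs of at least 4 neighbouring genes called in the same direction were chosen after their values were seen. Neighbours were counted among the genes tested.

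Depth ranged from 34322099 to 44755390 counts per library. A floor of 3 counts summed over a group corresponded to between 0.0225 and 0.0290 CPM. Folds against a group with 0 counts are lower bounds against that floor, which covers counting error only. Genes were filtered with filterByExpr, which left 13172, and scaled with TMM factors. Tests used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with 1 coefficient per group, all 12 libraries in the fit and Benjamini-Hochberg adjustment over the genes of a contrast. Because the spread between technical libraries is small (common dispersion 0.000172), a gene was called only at an adjusted p below 0.05 and an absolute log2 fold change of at least 1. On simulated counts with 200 changed genes, T3WT vs contWT recovered 92% of genes changed 3-fold, 96% at 4-fold and 94% at 8-fold. At 1.5-fold, which lies below the fold threshold of a call, it recovered 6%. It made 0 false calls among the unchanged genes of the 12728 tested. The simulated interaction recovered 90% of genes changed 3-fold and made 2 false calls.

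Chi-square tests compared every pair of libraries of a group. The statistic per gene was 1.26 to 1.88, and all pairs differed by more than sampling noise, with a largest p of 1.09e-78. The libraries were therefore counted separately. For genes with 20 to 2000 counts the statistic was 1.05 to 1.15. The expected overlap of call lists is the product of their sizes divided by the genes tested, per direction. Where comparisons share the contWT libraries, unchanged groups were simulated against them 10 times, with the spread between libraries of a pool only. The mitochondrial genes were tested as a set with camera at a preset correlation of 0.01, with camera at the estimated correlation, and with fry, all in limma 3.58.1. Neighbouring calls were compared with 10000 shuffles of the calls over genes.

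Alternatives chosen before the data were examined were size factors by relative log expression (RLE), no filter, a filter on at least 100 counts summed in a group, DESeq2 1.42.0, limma-voom, glmTreat, no fold threshold, a replicate block, fits with only the groups compared, and leaving out each library. Total-count scaling, omission of the 100 most abundant genes under either scaling and an absolute log2 fold change of at least 2 were added after seeing the data.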

Results

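Gene expression was counted in 12 libraries of tadpole intestine, 3 each labelled contWT, contHomo, T3WT and T3Homo. The design crosses genotype, wild type or TRα(-/-), with T3 treatment, and addresses how the loss of TRα, a nuclear receptor for thyroid hormone, changes the response of the larval intestine to T3. Library totals ranged from 35951142 to 38423895 counts in contWT, 34837299 to 40715696 in contHomo, 34322099 to 38421597 in T3WT and 40295245 to 44755390 in T3Homo. Errors are SD over n = 3 technical libraries throughout, unless given as SE. The libraries labelled T3WT had a broader set of detected genes, 15282 ± 46 with a count, against 14805 ± 52 in contWT, 14846 ± 63 in contHomo and 14805 ± 40 in T3Homo. The 100 most abundant genes took 45.1 ± 0.108% of counts in T3WT and group means of 48.9 to 49.8% elsewhere. The TMM scaling factor was 1.21 in T3WT and 0.921 to 0.962 in the other groups. The first principal component held 54.4% of the variance and the next 26.0%. The root mean square log2 difference between group means was 0.90 from T3WT to contWT, 0.93 from T3WT to contHomo and 0.87 from T3WT to T3Homo. It was 0.71 between contWT and T3Homo, 0.55 between contWT and contHomo and 0.54 between contHomo and T3Homo.

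In the libraries labelled T3WT, 1691 genes were higher and 677 lower than in contWT, 2368 of the 13172 genes tested. By the column labels this comparison is the T3 response of wild-type intestine, and by the titles it is the effect of losing TRα without T3. Rises outnumbered falls more strongly among large changes. Of the 641 genes changed at least 4-fold, 534 were higher and 107 lower, and at 16-fold the numbers were 86 and 14. At least 1 CPM was reached in T3WT alone by 451 genes, against 40 in contWT alone, 47 in contHomo alone and 37 in T3Homo alone. A total of 10449 genes reached 1 CPM in all 4 groups. At total-count scaling, 91.7% of the calls were higher, against 71.4% with TMM factors. The median log2 fold change of all genes was then 0.45 in place of 0.05. Without the fold threshold, 52.9% of the 10340 calls were higher.

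**Figure D1:**
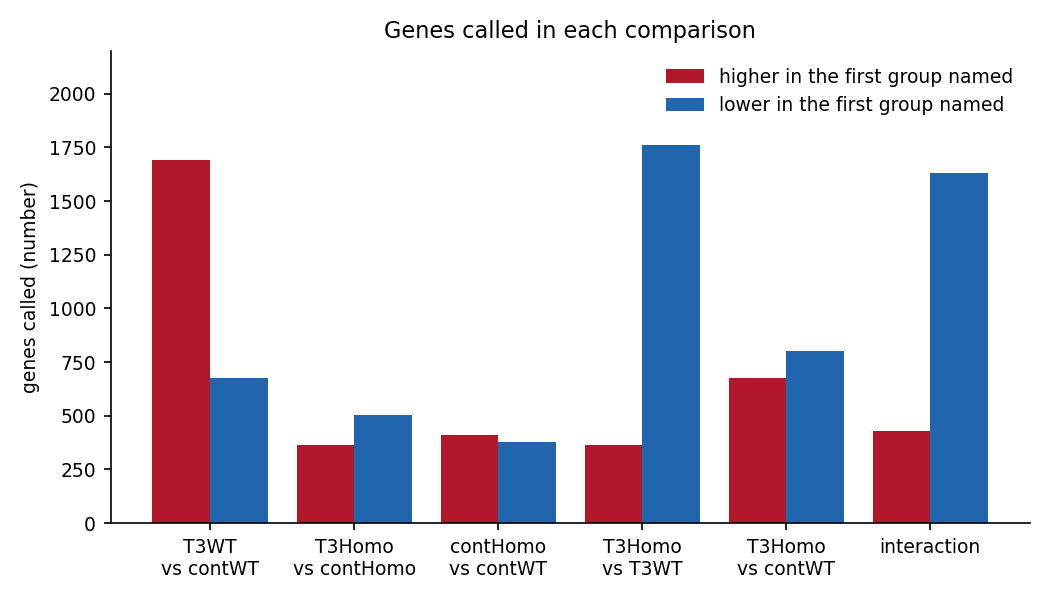
Bars give the number of genes called higher (red) or lower (blue) in the first group named, in each of the 6 contrasts (vertical axis, number of genes, from 0). T3WT vs contWT has 1691 higher and 677 lower genes, T3Homo vs contHomo has 365 and 505, and the interaction has 427 and 1632.

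The largest rises in T3WT vs contWT were genes with 0 counts in contWT. ENSXETG00000031386, a gene of 6 exons on the plus strand of scaffold GL172875.1 from 1635992 to 1647663, was at 17.2 ± 0.706 CPM in T3WT and at 0 CPM in contWT, at least 592-fold higher. Its level was 0.0465 ± 0.0311 CPM in contHomo, from 5 counts, and 1.19 ± 0.182 CPM in T3Homo. It was 25.6-fold higher in T3Homo than in contHomo, a fitted log2 fold change of 4.57 that was 5.23 without contHomo replicate 1, which held 3 of the 5 counts. Its level was 14.4-fold higher in T3WT than in T3Homo. ENSXETG00000012944, with 2 exons on the minus strand of GL173114.1 from 648500 to 685614, had 0 counts in all 6 contWT and contHomo libraries. It reached 17.0 ± 0.992 CPM in T3WT, at least 586-fold higher than contWT, and 7.55 ± 0.223 CPM in T3Homo, at least 269-fold higher than contHomo. Its level in T3WT was 2.25-fold that in T3Homo. It was the 1 gene of the 13172 with at least 1 CPM in T3WT and T3Homo and at most 3 counts per group in contWT and contHomo, and 0 genes had the reverse pattern. By the same limits, 7 genes were present in contWT and T3WT and not in contHomo and T3Homo, and 1 gene the reverse.

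The largest falls behaved differently from each other in the other comparisons. ENSXETG00000021234, on the minus strand of GL173096.1 from 99535 to 102097, went from 55.1 ± 1.97 CPM in contWT to 1.19 ± 0.193 in T3WT (log2 fold change -5.53 ± 0.07 SE, edgeR adjusted p = 3.25e-84). It was also low in contHomo, at 4.61 ± 0.554 CPM, and in T3Homo, at 0.722 ± 0.0441 CPM. ENSXETG00000017935, with 11 exons on the minus strand of GL172850.1 from 1150782 to 1167309, fell from 17.6 ± 0.725 CPM in contWT to 0.413 ± 0.0620 in T3WT (log2 fold change -5.41 ± 0.11 SE, edgeR adjusted p = 4.72e-66). It stood at 25.8 ± 1.07 CPM in contHomo and 17.7 ± 0.334 CPM in T3Homo.

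In the libraries labelled T3Homo, 365 genes were higher and 505 lower than in contHomo. By the column labels this is the T3 response of TRα(-/-) intestine, and by the titles it is the effect of losing TRα in the presence of T3. Changes of at least 4-fold were seen in 56 higher and 89 lower genes. Of the genes called in T3WT vs contWT, 223 were called higher in both comparisons and 120 lower in both, where independent lists would share 46.9 and 26.0. Opposite calls were made for 107 genes, against 83.6 for independent lists. Across the 2788 genes called in either comparison, the log2 fold changes had a correlation of 0.36 and a slope of 0.22. Genes are not independent replicates. These comparisons share no library.

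Most genes that rose in T3WT vs contWT had a smaller change in T3Homo vs contHomo. The contWT and T3WT libraries that define the rise also enter the interaction. Choosing genes by their change in T3WT vs contWT thus favours a smaller change elsewhere, and the shares and medians of chosen genes carry this selection. Of the genes called in T3Homo vs contHomo, 420 were not called in T3WT vs contWT. The interaction was called for 2059 genes, 427 (20.7%) with a positive and 1632 with a negative difference. Without the fold threshold 53.0% of the 8471 calls were positive, and at total-count scaling 6.68% of calls were. Of the 1691 genes higher in T3WT, 1078 (63.7%) had a called smaller change. The median log2 fold change of all 1691 genes was 1.57 in T3WT vs contWT and 0.20 in T3Homo vs contHomo. With genes at 0 counts set to their floor, these medians were 1.57 and 0.19. Of the 677 genes lower in T3WT, 276 (40.8%) had a called smaller change and 7 a larger one. The median of all 677 was -1.29 in T3WT vs contWT and -0.36 in T3Homo vs contHomo. At adjusted p below 0.05 without the fold threshold, the shares with a smaller change were 80.5% of the rises and 83.8% of the falls. The negative interaction calls also held 547 genes not called in T3WT vs contWT. ENSXETG00000021234 had an interaction log2 fold change of 2.87 ± 0.23 (SE, edgeR adjusted p = 2.74e-20). For ENSXETG00000017935 it was 4.86 ± 0.13 (SE, edgeR adjusted p = 3.45e-55). Under glmTreat, which tests against a log2 fold change of 1, 1016 interaction calls were made.

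**Figure D2:**
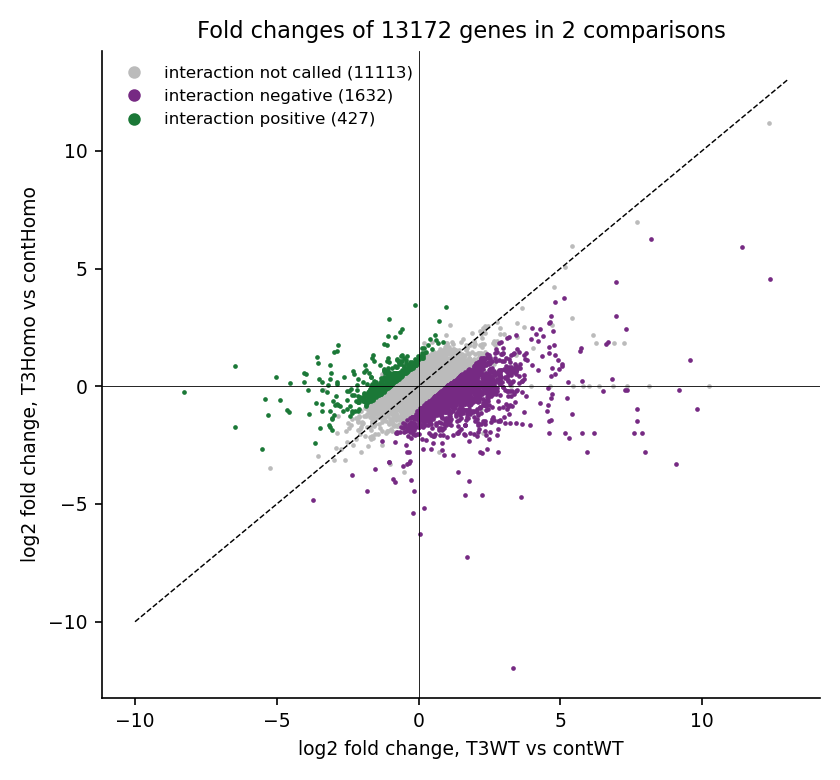
Each point is 1 of the 13172 genes tested, with its log2 fold change in T3WT vs contWT (horizontal) and in T3Homo vs contHomo (vertical), and the dashed line marks equal changes. The 1632 genes with a called negative interaction (purple) lie below the line and the 427 with a positive one (green) above it.

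The libraries labelled contHomo and contWT differed in 787 genes, 409 higher and 378 lower in contHomo. By the column labels this is the effect of losing TRα without T3, and by the titles it is the T3 response of wild-type intestine. A block of 7 neighbouring genes on scaffold GL172646.1, from 5071172 to 5183110, was lower in contHomo at all 7 members, with a median log2 fold change of -3.47. Their summed level was 118.6 ± 0.742 CPM in contWT, 15.5 ± 0.363 in contHomo, 37.2 ± 0.724 in T3WT and 8.12 ± 0.646 in T3Homo. All 7 were also called lower in T3Homo than in T3WT, with a median of -3.10. In T3WT vs contWT 5 of the 7 were called lower, and in T3Homo vs contHomo 4 of the 7. The 6 tested genes flanking the block had a median of -0.21 in contHomo vs contWT, within a range of -0.94 to 0.33. In T3Homo vs T3WT 2 of these 6 were called lower (median -0.48), and the run of lower genes there held 9 genes, from 5071172 to 5255344. In T3WT vs contWT 3 of the 6 were called higher. Exons of equal length recur among the 7 genes, with 1 length found in 4 of them. Levels of single members are uncertain where copies share reads, so the sum is given. The span of the block holds 8 annotated genes, of which 7 were tested, and 56 counts fell outside the genes tested.

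**Figure D3:**
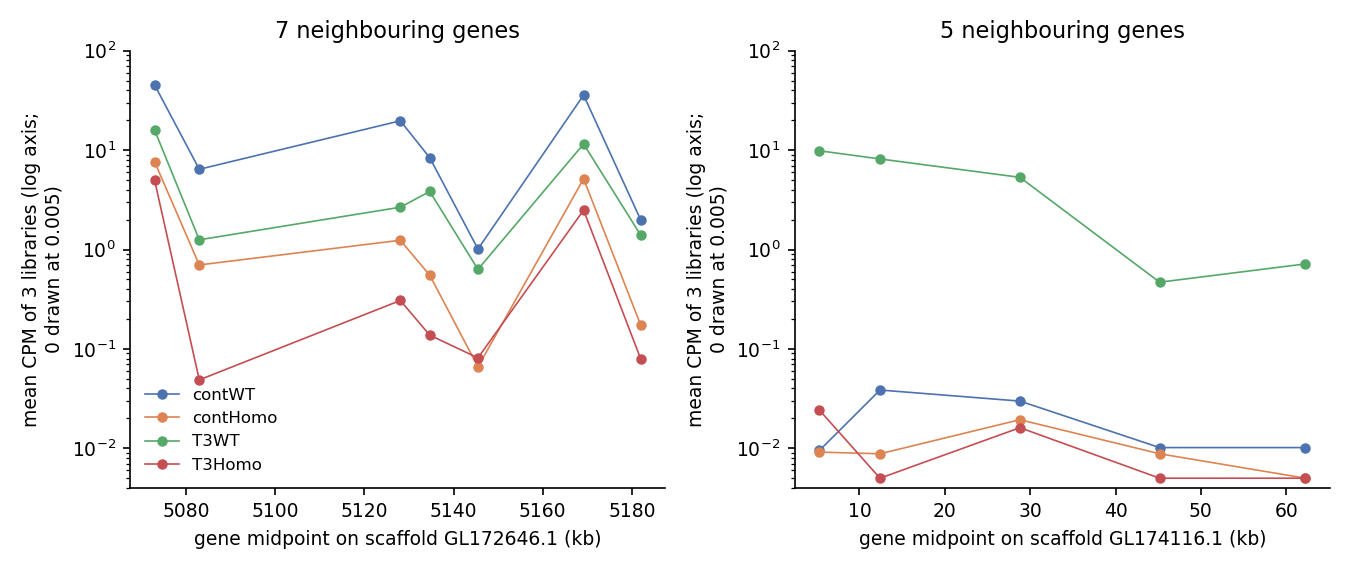
Points give mean CPM over 3 libraries (log axis, 0 drawn at 0.005) of neighbouring genes at their midpoints in kb, for 7 genes on GL172646.1 (left) and 5 genes on GL174116.1 (right), coloured by group. The summed level of the 7 genes is 118.6 CPM in contWT and 15.5 in contHomo, and that of the 5 genes is 24.5 CPM in T3WT and at most 0.0983 CPM in the other groups.

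A second block, 5 genes on scaffold GL174116.1 from 4232 to 63176, was counted almost entirely in T3WT. Its summed level was 24.5 ± 0.975 CPM there, from 3269 counts. It was 0.0983 ± 0.0637 CPM in contWT, 0.0462 ± 0.0134 in contHomo and 0.0403 ± 0.0698 in T3Homo, from 10, 5 and 5 counts. All 5 genes were called higher in T3WT than in contWT and lower in T3Homo than in T3WT. The difference between T3WT vs contWT and T3Homo vs contHomo was called for 4 of the 5. Exon lengths of 254 and 137 bases were each found in 4 of these 5 genes. Levels of single members are uncertain here too if the genes are copies that share reads, which was not tested. This span holds 6 annotated genes, of which 5 were tested. A run of 4 genes on GL173371.1, from 246262 to 294833, changed in opposite directions. Its median log2 fold change was 1.73 in T3WT vs contWT and -1.83 in T3Homo vs contHomo.

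The libraries labelled T3Homo had 364 genes higher and 1761 lower than T3WT. By the column labels this is the effect of losing TRα with T3, and by the titles it is the T3 response of TRα(-/-) intestine. Of the 535 genes changed at least 4-fold, 479 were lower. At total-count scaling 6.40% of the calls were higher, against 17.1% with TMM factors, and the median of all genes was -0.35 in place of -0.02. Without the fold threshold, 48.9% of the 10026 calls were higher. In contHomo vs contWT and T3Homo vs T3WT, 230 genes were lower in both and 53 higher in both, where independent lists would share 50.5 and 11.3. Opposite calls were made for 106 genes, against 65.1. All labels agree on the identity of T3Homo and contWT, TRα(-/-) with T3 and wild type without. Between these, 1478 genes were called, 674 higher and 804 lower in T3Homo. The numbers of genes changed at least 4-fold were 135 and 213.

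The 13 protein-coding genes of mitochondrial DNA, which encode subunits of respiratory complexes and ATP synthase, took a larger share of counts in T3WT. The share was 3.03 ± 0.0653% there, 1.93 ± 0.0256% in contWT, 1.87 ± 0.0229% in contHomo and 1.71 ± 0.0142% in T3Homo. With TMM factors, 10 of the 13 rose in T3WT vs contWT at adjusted p below 0.05, 1 fell and 2 did not pass, with a median log2 fold change of 0.30. With RLE factors 10 rose, 2 fell and 1 did not pass, and at total-count scaling all 13 rose, with a median of 0.69 where that of all genes was 0.45. COX2, a cytochrome c oxidase subunit, went from 4926 ± 134 to 6710 ± 164 CPM, and CYTB, of complex III, had a log2 fold change of 0.30. ND2, the member that fell, had -0.09, and at total-count scaling it was 0.31. In T3Homo vs contHomo 12 of the 13 fell, with a median of -0.19, and ATP8 did not pass. With RLE factors all 13 fell, and at total-count scaling 11 fell, where ND4L did not pass either. Without contHomo replicate 1, and likewise without T3Homo replicate 2, 11 fell, and ATP8 and ND4L did not pass. In the interaction all 13 passed with edgeR, each negative, with a median of -0.42. With DESeq2 12 of the 13 passed, and ND2 did not, at an adjusted p of 0.074. Over the other alternatives its adjusted p was at most 0.018. These changes were below the 2-fold threshold, with log2 fold changes from -0.09 to 0.45 in T3WT vs contWT and from -0.58 to -0.11 in the interaction. Camera gave adjusted p = 3.89e-09 for the interaction at the preset correlation, and adjusted p = 0.13 with an estimated correlation, and the lowest adjusted p over the 6 contrasts was 0.13 in that test. Fry, which tests the 13 genes without comparing them with others, gave adjusted p = 3.16e-06 for the interaction.

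**Figure D4:**
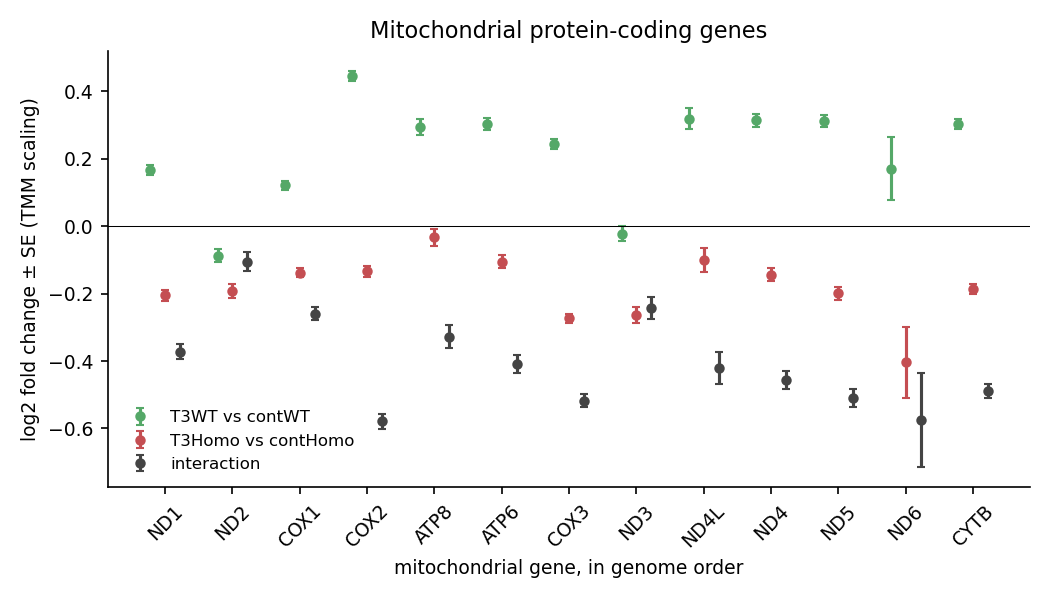
Points give the log2 fold change with its SE (vertical, TMM scaling) of the 13 mitochondrial protein-coding genes (horizontal, genome order) in T3WT vs contWT, T3Homo vs contHomo and the interaction, from 3 libraries per group. All 13 interaction values lie below 0, with a median of -0.42.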

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

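The dilution test and the splits of 3 with 3 libraries were set out before their results were seen, as was the count of regroupings for the interaction. The division of those regroupings by whether they kept T3WT together, and the tests without the 100 most abundant genes, on genes that rose, exchanged labels, the gene block and the mitochondrial genes were chosen only after the result was seen.

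The 2059 interaction calls were flagged because the T3WT vs contWT and T3Homo vs contHomo changes differed by a test of the difference. Of 100 regroupings of the 12 libraries, the real one included, 1 gave as many calls, and the highest other gave 2032. The 8 other regroupings that kept the 3 T3WT libraries together gave 888 to 2032 calls, and the 91 that parted them at most 278. Regroupings with many calls were thus those that kept T3WT whole, a structure of the samples. Parting near-identical technical libraries was bound to leave few calls, and with 9 regroupings that keep T3WT together, the real one included, chance cannot be excluded.

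T3WT vs contWT had 2368 calls and T3Homo vs contHomo 870. The 100 most abundant genes are argued against as the whole cause, since at total-count scaling their omission moved the median log2 fold change of all genes in T3WT vs contWT from 0.45 to 0.32 and left 2839 calls, against 870. For the genes that fell, dilution by RNA of another tissue that lacks the genes abundant in contWT was tested at 1 size only. It is argued against where it would lower those genes at least 2-fold at total-count scaling. Of the 500 most abundant contWT genes, 5.8% were at least 2-fold lower at total-count scaling. The falls were called with TMM factors, 1.21 in T3WT and 0.921 in contWT. A smaller dilution could therefore give such calls and stays open. The test cannot decide on a tissue that also expresses those genes, since admixture would not lower them. Nor can it decide on a tissue lost from the T3WT pool. Dilution also stays open for the genes that rose, such as the 451 with 1 CPM or more in T3WT alone. No gene names were at hand to recognise a tissue. Exchanged labels stay open too, since the 2059 interaction calls are the same under both readings, and so does a difference in T3 response with genotype, because each group is 1 pool.

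The 7 genes on GL172646.1 were low in both groups labelled Homo. Reads traded among these 7 genes would leave their sum unchanged, but the summed level had a log2 ratio of -2.93 in contHomo to contWT. Reads lost to copies outside the block stay open, since the handling of reads with several alignments is not given. A sequence variant or a missing copy in the tadpoles labelled Homo, possibly linked to the genotype, stays open too. The T3Homo to T3WT ratio was -2.20, a difference of 0.74 from the other ratio, which changes of real expression with T3 could add. Under the titles both low groups had received T3, so hormone treatment is an open explanation as well.

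All 13 mitochondrial genes were flagged for a negative interaction with edgeR, of which ND2 did not pass with DESeq2. Scaling is argued against, since the median interaction nearest to 0 under TMM, RLE and total-count scaling was -0.42. A shift of equal size in all genes is argued against too, since the median of the 13 minus that of all genes was -0.43. A scaling factor shifts both alike, so the choice of scaling could not change this difference. Camera at the estimated correlation, which compares the 13 with the other genes, did not pass for the interaction (adjusted p = 0.13). Whether the 13 stand apart from other genes as a set therefore stays open. A biological difference between the pools and uneven RNA quality were not tested and stay open.

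The interaction also flagged ENSXETG00000021234 at a log2 fold change of 2.87 and ENSXETG00000017935 at 4.86. It was called for 4 of the 5 genes on GL174116.1, whose summed counts were at most 10 in each of the other 3 groups.

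The comparisons of 3 with 3 libraries allow 10 splits, too few for a share under 0.05. All splits but the real one mix libraries of both pools in a group. Parting near-identical technical libraries was bound to leave few calls, so these counts cannot decide on chance. The real split, 1 of the 10 in each case, gave 2368, 870, 787, 2125 and 1478 calls, in the order T3WT vs contWT, T3Homo vs contHomo, contHomo vs contWT, T3Homo vs T3WT and T3Homo vs contWT, and the highest other split gave 0 in each.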

How the results depend on the processing

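Total-count scaling, omission of the 100 most abundant genes under either scaling and the 4-fold threshold were chosen after seeing the data. The counts of calls stayed within 1.5 times of the reported ones under RLE factors, both other filters, DESeq2, limma-voom, fits of only the groups compared, total-count scaling, omission of the 100 most abundant genes and leaving out each library. The genes called were not all the same. The filter on at least 100 counts kept from 73.7% of the reported calls in contHomo vs contWT to 80.6% in the interaction. Total-count scaling kept 82.9% in T3WT vs contWT. Without a fold threshold, calls numbered 10340 in T3WT vs contWT, 8351 in T3Homo vs contHomo, 6983 in contHomo vs contWT, 10026 in T3Homo vs T3WT, 9049 in T3Homo vs contWT and 8471 in the interaction, and 5124 were shared in direction by the first 2. With glmTreat against a log2 fold change of 1 the numbers were 1470, 369, 355, 1340, 794, 1016 and 144. At 4-fold they were 641 and 145 in the first 2, with 59 shared. These follow from the thresholds themselves.

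The majority direction turned without a fold threshold, to 51.0% of calls higher in T3Homo vs contHomo, 46.2% in contHomo vs contWT, 50.2% in T3Homo vs contWT and 53.0% in the interaction. It turned at total-count scaling to 50.8% in T3Homo vs contWT. T3WT vs contWT came to 52.9% and T3Homo vs T3WT to 48.9% higher without a fold threshold, from 71.4% and 17.1%. The interaction had 6.68% of calls higher at total-count scaling, against 20.7%. ND2 and ND3 in T3WT vs contWT were positive at total-count scaling, at 0.31 and 0.37, and at 0.18 and 0.25 when the 100 most abundant genes were also left out. In that setting 87.7% of calls in T3WT vs contWT were higher. With RLE factors ND3 in T3WT vs contWT and ATP8 in T3Homo vs contHomo passed as lower. With DESeq2 ND2 in the interaction did not pass, at -0.10. At total-count scaling the turns of ND2 and ND3 follow from leaving out the TMM factors, 1.21 in T3WT and 0.921 in contWT. The turn of T3Homo vs contWT and the move of the interaction to 6.68% come with the same step. The median of all genes was then 0.06 and -0.34. The turns without a fold threshold come with the added genes changed less than 2-fold. Why those genes lean another way was not tested.

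Replicate numbers do not pair the libraries. Of the 18 pairs with the same number, 6 had a correlation of deviations over 0.1, and 4 of the 12 libraries matched their own number best. With the replicate block the calls were 2374, 872, 782, 2125, 1473 and 2048, and 344 were shared by the first 2 contrasts. The gene list tests and the label check were not run, for lack of gene names. At this depth 96% of simulated 4-fold changes were recovered in T3WT vs contWT, but technical libraries do not measure the spread between animals.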

Other observations

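All tests in these paragraphs were chosen only after the result was seen. Genes called in the same direction lay next to each other more often than shuffled calls did. In T3Homo vs contHomo 64 neighbouring pairs were called in the same direction, against a mean of 25.6 over 10000 shuffles. In contHomo vs contWT there were 51 against 20.4, and in T3WT vs contWT 281 against 219.0. The permutation p was 1e-04 in each, the smallest the shuffles can give, with an adjusted p of 0.00012 over 6 contrasts. The shuffles do not account for neighbouring copies that share reads or for overlapping genes whose reads cannot be separated.

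Genes annotated with a single exon were called more often than other genes in several directions, by Fisher's exact test with adjustment over 6 tests. Of the single-exon genes, 9.89% were called lower in T3WT vs contWT, against 4.97% of other genes (odds ratio 2.10, adjusted p = 6.73e-05). In T3Homo vs contHomo 4.95% were called higher, against 2.69% (adjusted p = 0.013), and 6.67% lower, against 3.73% (adjusted p = 0.0057). Genes of 2 exons had 4.93% higher and 4.93% lower there, so the rises were not particular to single-exon genes. A positive interaction was called in 7.96% against 3.07% (odds ratio 2.73, adjusted p = 3.57e-06). That share fell with exon number, to 4.62% at 2 exons and 1.98% at over 20 exons. Expression level and gene length were not adjusted for. The tests for genes called higher in T3WT vs contWT, 14.4% of single-exon and 12.8% of other genes (adjusted p = 0.35), and for a negative interaction, 13.5% and 12.3% (adjusted p = 0.43), did not pass.

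Of the genes higher in T3WT than contWT, 272 were also called higher in contHomo than contWT, where independent lists would share 52.5. For calls lower in both the numbers were 92 and 19.4, and for opposite calls 97 and 69.5. The median log2 fold change in contHomo vs contWT of the 1691 genes higher in T3WT was 0.18. Both comparisons use the contWT libraries, which come from 1 pool, and any deviation of that pool enters both. The covariance of the fold changes was 0.141, against 1.15e-05 with 0 shared calls for simulated unchanged groups, a difference of 0.141. The simulation holds only the spread between libraries of a pool, so it cannot decide whether the shared pool accounts for the overlap, and the controls are too few to split. A candidate explanation is that the receptor without T3 holds down genes that T3 raises, so that its loss lifts them. The shift of 0.18 cannot decide this either, because of the shared pool and because the labels disagree on which of contHomo and T3WT lacks the receptor.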
